A study of Homo sapiens with 6 samples.

How the data were processed

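Poly-A RNA was sequenced from 6 cultures of one edited human WTC11 induced pluripotent stem cell line, after differentiation with a commercial kit for atrial cardiomyocytes. The labels put 3 cultures in the DMSO group and 3 in the dTAGv-1 group (500 nM, added on day 20 for 24 h). Each replicate was 1 culture well, and the design text calls the replicates biological. Whether the wells came from separate differentiations is not given in the sources used here, so p-values measure the spread between these wells. The cDNA was primed with random hexamers, per the labels' protocols.

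The authors deposited a table of read counts per gene and a table of FPKM, each with 58735 genes and 1 column per library. Per the submitters' processing notes, HISAT2, featureCounts 2.0.6, DESeq2 1.42.0 and the hg38 genome were used. The notes give neither roles nor order, and no HISAT2 version. The strand setting of the counting is not given in the sources used here. The deposited counts were whole numbers. The deposited FPKM values equalled the count divided by the gene length in the file and by 1 constant per library, which was 0.968 to 1.035 of the library's total count; how this constant was set is not stated. Gene identifiers, starts and ends matched GENCODE release 29 for 58735 of 58735 genes.

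Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the groups (minimum count 10, minimum total count 15), which left 19640. Libraries were scaled by TMM factors. The groups were compared with the edgeR quasi-likelihood test, fitted robustly with the group as the single term. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the tested genes, and the threshold was an adjusted p of 0.05. The standard error of a log2 fold change was taken from the F statistic of that test. Levels are CPM, counts scaled to the library size and the TMM factor, given as mean ± SD over 3 libraries per group. Every adjusted p of a gene comes from edgeR unless another tool is named.

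Before the data were examined, 37 gene lists, the rule for the named genes, the tests and most of the alternatives were written down. Of 644 list symbols, 642 matched a gene name in the file and 2 matched through a reference table of symbols. Lists with at least 5 tested members, 35 in all, were compared with the other tested genes by camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and p-values were adjusted over the lists. A repeat of camera estimated the correlation from the 6 libraries, and fry tested whether the genes of a list moved, on balance, one way. With an estimated correlation camera also limits its degrees of freedom to the few left by the 6 libraries. A call lost in this repeat can therefore come from either change. Intervals of list medians are 95% bootstrap intervals from 2000 resamples of the members, so they do not measure the spread between libraries. The lists for the TBX5 locus neighbours and for macrophages and blood had too few tested members for camera.

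Named genes are TBX5, NPPA, GATA4 and NKX2-5; the 10 protein-coding genes in each direction with the largest fold among those with an adjusted p under 0.05, a mean of at least 5 CPM and no overlap between the groups; the 5 protein-coding genes in each direction with the smallest p; and up to 4 members of each list with the smallest p among those past the threshold, or up to 2 where none passed. All members of the list of TBX5-dependent genes reported elsewhere were also open to naming. A gene named outside this rule is marked as chosen after its values were seen. Results of 3 genes that the rule covers are not reported here, although they remain in the counts.

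Replicate numbers in the labels run from 1 to 3 in both groups, and the labels do not say what a number shares. The deviations of same-numbered libraries from their group means correlated at 0.12, 0.20 and 0.29 across genes, against -0.23 to 0.06 for the other pairings. Equal numbers were therefore taken to pair the libraries, and this pairing rests on the data. The main fit had been fixed with the group alone and does not use the pairing, so the main counts and calls ignore it. A fit with the replicate number as a block is given beside a result where it changed a call or moved a count by over 1.5 times. Replicates were also checked for duplicates. Chi-square per degree of freedom between libraries of one group was 11.6 to 52.7, so no 2 libraries of a group were the same within sampling noise. Libraries of different groups were not compared in this way.

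Other settings fixed in advance were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of 5 CPM in 3 libraries, protein-coding genes alone, the deposited FPKM with a pseudocount of 1 or 0.1 in limma-trend, the replicate block, each library left out in turn, and both other set tests. Chosen after seeing the data were leaving out both libraries numbered 3, thinning every library to the smallest total, removing a trend on GC content and transcript length from each library, and that removal together with the block. GC content and length came from the longest GENCODE 29 transcript of each gene, for 19635 of the 19640 tested genes. Cells with an untagged TBX5 given the ligand are not analysed here, and no protein level was measured.

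The gene test was tried on simulated data, in 10 simulations of 3 against 3 libraries with the real means and library sizes. Each had 200 changed genes, and 19087 to 19144 genes were in the fit. The test recovered 41.8% of the genes changed 1.5-fold (280 of 670), 70.1% of those changed 2-fold (470 of 670) and 89.7% of those changed 4-fold (592 of 660). No changed gene was called in the wrong direction, and 170 calls, 11.2% of the total, were false, above the nominal 5%. The list test was tried on a separate simulated data set, where a planted list was called and 0 of 29 lists without a shifted gene were. Genes were drawn there independently of each other. In the real libraries the estimated correlation was 0.363 for sarcomere and 0.356 for proliferation genes. The 0 of 29 therefore does not show how the list test behaves with correlated genes. Lists were also called in splits of the real libraries that mixed the groups, as given at the end.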

Results

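Gene expression was measured by RNA sequencing in human atrial-type cardiomyocyte cultures in which the transcription factor TBX5 can be degraded on demand. TBX5 is a T-box factor of atrial and conduction tissue, and heterozygous loss of it underlies Holt-Oram syndrome. The cultures came from WTC11, an established induced pluripotent stem cell line, edited so that endogenous TBX5 carries an FKBP12 variant and an HA epitope at its N-terminus. dTAGv-1 is a ligand that bridges the FKBP12 variant and the VHL ubiquitin ligase and so directs the tagged protein to the proteasome. On day 20, 3 cultures received 500 nM dTAGv-1 and 3 received the vehicle DMSO, both for 24 h. The comparison addresses which transcripts change within a day of ligand addition. The series title places it in a study of how sensitive chromatin folding is to the dose of a factor tied to heart disease.

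Total counts were 27226382, 33913051 and 33546490 in DMSO replicates 1, 2 and 3 and 34777173, 48327844 and 34696908 in dTAGv-1 replicates 1, 2 and 3, so every dTAGv-1 library was deeper than every DMSO library. Of 58735 genes in the count table, 32946 had a read in at least 1 library and 19640 were tested. Mitochondrially encoded transcripts took 14.3, 10.5 and 10.2% of the counts with DMSO and 12.5, 10.8 and 13.9% with dTAGv-1. The first principal component, with 29.9% of the variance, separated the groups. The second, with 27.5%, separated both libraries numbered 3 from the other 4.

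TBX5 mRNA rose under dTAGv-1, from 144 ± 22.2 CPM to 234 ± 17.9 CPM (SD, n = 3 per group), a log2 fold change of 0.70 ± 0.11 (SE, edgeR adjusted p = 0.0040). The gene (ENSG00000089225) lies on the minus strand of hg38 chromosome 12, from 114353931 to 114408442. All 3 dTAGv-1 libraries lay above all 3 DMSO libraries. The ligand acts on the tagged protein, which RNA sequencing does not measure, so the mRNA level neither shows nor excludes degradation. The divergent long noncoding gene TBX5-AS1 (ENSG00000255399, plus strand, 114408191 to 114412831) also rose, from 25.4 ± 8.10 to 51.0 ± 3.32 CPM, a log2 fold change of 1.00 ± 0.20 (adjusted p = 0.030). The exons of both genes share 252 bases. Without DMSO replicate 1, or without dTAGv-1 replicate 1, 2 or 3, TBX5-AS1 kept its fold and its adjusted p was 0.0947, 0.0972, 0.102 and 0.0845. Of the 4 tested neighbours of TBX5, TBX5-AS1 alone passed (1 rose and 1 fell when adjusted over the list alone). The partner factors GATA4 and NKX2-5 did not pass: GATA4 was at 266 ± 38.2 and 313 ± 17.1 CPM (log2 fold change 0.23 ± 0.11, adjusted p = 0.24) and NKX2-5 at 295 ± 54.8 and 296 ± 34.4 CPM. GATA4 passed with the replicate block (0.24, adjusted p = 0.0057) and without DMSO replicate 3 (0.38, adjusted p = 0.0146).

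Among protein-coding genes past the threshold with a mean of at least 5 CPM and no overlap between the groups, the 10 largest falls included natriuretic peptide and striated-muscle genes. NPPA, which encodes atrial natriuretic peptide (ENSG00000175206, chromosome 1, 11845709 to 11848345), fell 8.57-fold, from 148 ± 51.8 to 17.3 ± 2.28 CPM (log2 fold change -3.10 ± 0.27, adjusted p = 0.0030). Its neighbour NPPB, for B-type natriuretic peptide, fell 5.05-fold, from 13.8 ± 6.14 to 2.74 ± 0.584 CPM. CORIN, the protease that processes the NPPA precursor and not among these 10, fell 3.24-fold, from 95.3 ± 11.1 to 29.4 ± 1.13 CPM. ACTA1, skeletal alpha-actin, fell 6.37-fold, and MYL2, the ventricular regulatory light chain, fell 5.85-fold. MYH7, the slow beta-myosin heavy chain (ENSG00000092054, chromosome 14, 23412738 to 23435718), fell 4.12-fold, from 761 ± 139 to 184 ± 22.5 CPM. TFPI2, RRAD, ADAM11, HES7 and SYNGR3 completed the 10, with log2 fold changes of -2.26, -2.14, -2.08, -2.06 and -1.96. HES7 did not pass without dTAGv-1 replicate 2 (adjusted p = 0.0818). Among the falls with the smallest p were FHL2, a LIM-domain cofactor, and KCNIP2, the subunit of the transient outward potassium current, at 3.45-fold and 3.43-fold.

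Under the same limits the largest rises were smaller. PLPPR4, a phospholipid phosphatase-related membrane protein, rose 3.04-fold, from 6.81 ± 1.17 to 20.7 ± 2.16 CPM (log2 fold change 1.60 ± 0.16, adjusted p = 0.00022), and AKAP5, a kinase anchoring protein, rose 2.39-fold. ARHGAP20, SUSD5, GBP4, BEX1, UHRF1 and CMTM5 rose by 1.25, 1.23, 1.22, 1.20, 1.20 and 1.14 on the log2 scale. UHRF1 maintains DNA methylation through replication. BRI3BP and DNAH2, at 1.12 and 1.10, completed the 10 largest. BRI3BP did not pass without dTAGv-1 replicate 1 (adjusted p = 0.081) or 3 (0.0693), and DNAH2, at an adjusted p of 0.0497, did not pass when DMSO replicate 1 or 3 or any dTAGv-1 replicate was left out (adjusted p up to 0.19). Rises with small p included the splicing factor HNRNPM (103 ± 1.16 to 206 ± 7.64 CPM), LRRN3, the immediate early factor EGR1 (82.7 ± 11.4 to 173 ± 1.14 CPM) and the hyaluronan synthase HAS2.

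In total, 482 genes rose and 675 fell, of which 48 and 139 changed at least 2-fold. Protein-coding genes made up 458 of the rises and 636 of the falls. In simulated data with 200 changed genes, drawn independently and without an effect of the replicate number, 11.2% of the calls were false. That share need not hold for the 1157 genes called here. The median fold was 1.446 among the genes that rose and 1.531 among those that fell. In all 1157 genes the values of the groups did not overlap, as they did not in 26.72% of all tested genes, where chance gives 10% for 3 against 3. With the replicate block, 1625 genes rose and 2084 fell, 131 and 238 of them at least 2-fold. From the deposited FPKM with a pseudocount of 0.1 the counts were 313 and 290, and with the block and the GC and length trend removed they were 2171 and 1716, so in both the falls were no longer the majority. Nor were they from FPKM with a pseudocount of 1 (306 and 298), with the GC and length trend removed (432 and 426) or without DMSO replicate 3 (895 and 870). The counts depended on single libraries: rises numbered 165 without DMSO replicate 2, 895 without DMSO replicate 3, and 117, 149 and 180 without dTAGv-1 replicates 1, 2 and 3, and falls numbered 434 and 311 without DMSO replicates 1 and 2, and 209, 215 and 298 without dTAGv-1 replicates 1, 2 and 3. At least 2-fold, rises numbered 75 without DMSO replicate 3 and 24, 31 and 28 without dTAGv-1 replicates 1, 2 and 3. Falls of that size numbered 84 and 87 without dTAGv-1 replicates 1 and 2. Each fit that left out 1 library used the group alone, so it also left the same-numbered partner unmatched. It had fewer libraries as well, so a lost call can reflect lower power and not reliance on the library left out. All calls that such a fit shared with the main fit kept their direction, as did 322 of 322 without dTAGv-1 replicate 1. The block kept 99.9% of the main calls. Without both libraries numbered 3, 680 genes rose and 814 fell, and 80.1% of the main calls were kept.

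**Figure D1:**
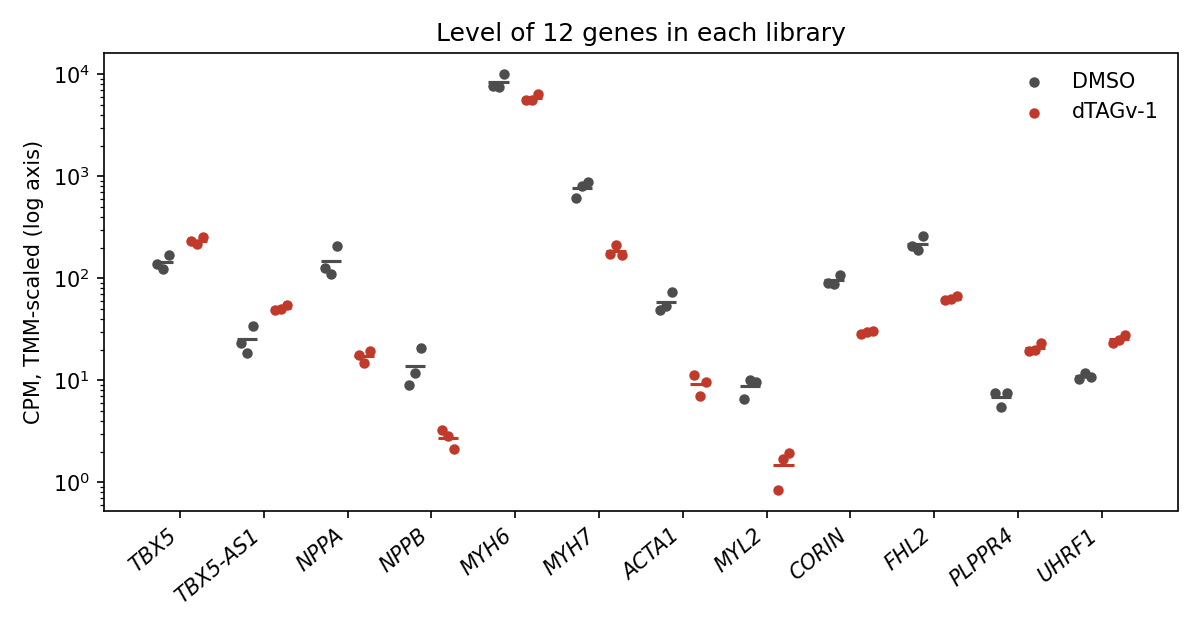
Level of 12 genes in each of the 6 libraries, in TMM-scaled CPM on a log axis, with DMSO in grey and dTAGv-1 in red; points are libraries and bars are group means (n = 3). NPPA fell from a mean of 148 to 17.3 CPM and MYH7 from 761 to 184 CPM, whereas TBX5 rose from 144 to 234 CPM.

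**Figure D2:**
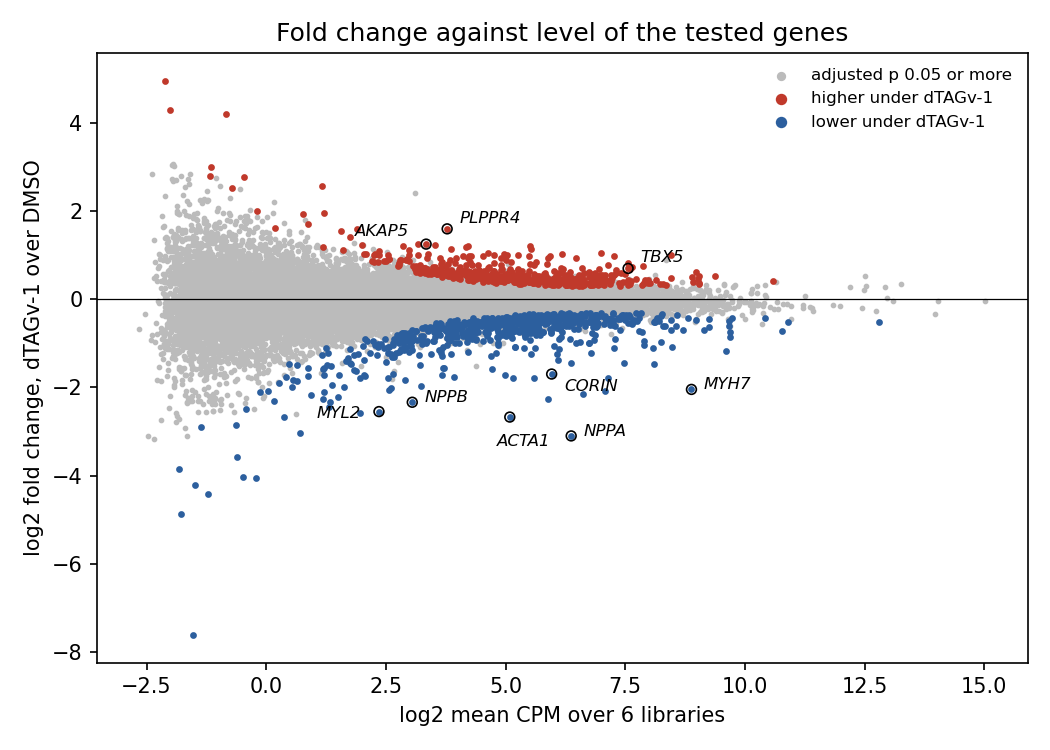
Log2 fold change of dTAGv-1 over DMSO against log2 mean CPM for the 19640 tested genes, with genes at an adjusted p under 0.05 in red (482 higher) and blue (675 lower) and the rest in grey. Circled genes are named; NPPA, ACTA1 and MYL2 lie at -3.10, -2.67 and -2.55.

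Genes reported elsewhere to depend on TBX5 fell as a list: of 19 tested members, 7 fell, 0 rose and 12 did not pass (9 fell when adjusted over the list alone). The median log2 fold change was -0.34, and camera gave an adjusted p of 2.94e-06. With an estimated correlation the adjusted p was 0.542. Beside NPPA and NPPB, those that fell included FHL2, the endoplasmic reticulum protein TECRL (369 ± 39.2 to 172 ± 5.23 CPM), the atrial connexin GJA5 (9.03 ± 2.17 to 2.63 ± 0.0798 CPM) and MYH6, the alpha-myosin heavy chain. MYH6 had an adjusted p of 0.043 and did not pass when any 1 of the 6 libraries was left out (adjusted p up to 0.208). Members that did not pass included RYR2 (-0.65), ATP2A2 (-0.28), PLN (-0.23), GJA1 (-0.22) and SLN (-0.34), and values near 0 were found for DSP (-0.09), SMYD1 (0.04) and ID2 (0.11). With the replicate block, 12 members fell and 1 rose: RYR2 (-0.65, adjusted p = 1.37e-08), SLN (-0.34, 0.000568), ATP2A2 (-0.27, 0.00194), GJA1 (-0.22, 0.0108) and PLN (-0.22, 0.0228) then passed as falls. RYR2 also passed without dTAGv-1 replicate 3 (-0.83, adjusted p = 0.0483), and 1 member rose without DMSO replicate 3.

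Atrial and ventricular markers were both called lower as lists. Of 19 atrial markers, 5 fell, 2 rose and 12 did not pass (11 and 3 when adjusted over the list alone; camera adjusted p = 0.00663, and adjusted p = 0.669 with an estimated correlation). NPPA, GJA5 and the Notch effector HEY1 (95.8 ± 14.6 to 43.7 ± 5.35 CPM) fell, while CHRM2, the muscarinic receptor of atrial muscle, rose from 145 ± 11.9 to 215 ± 6.0 CPM. The other changed members, chosen after their values were seen, were KCNA5 (-0.73), PAM (-0.61) and KCNJ5 (0.64). KCNA5 did not pass when any library but dTAGv-1 replicate 3 was left out (adjusted p up to 0.155), nor KCNJ5 when any but DMSO replicate 3 was (up to 0.0802), where 1 atrial marker rose, nor PAM without each dTAGv-1 replicate (up to 0.092). Of 16 ventricular markers, 5 fell, 0 rose and 11 did not pass (8 fell and 1 rose when adjusted over the list alone; camera adjusted p = 0.00014, and adjusted p = 0.286 with an estimated correlation). These were MYL2, MYH7, FHL2, MYL3 and CKM. MYL3 did not pass without dTAGv-1 replicate 1 (adjusted p = 0.0564) or 2 (0.0511), nor did CKM (0.107 and 0.109). With the block, 11 atrial markers fell and 3 rose, and 9 ventricular markers fell and 2 rose. The atrial list was not called without DMSO replicate 3 (adjusted p = 0.113), and its falls numbered 3 without dTAGv-1 replicate 1 and 3 without replicate 2. Ventricular falls numbered 3 without dTAGv-1 replicate 1.

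Sarcomere transcripts fell as a list. Of 30 tested members, 13 fell, 0 rose and 17 did not pass (18 fell when adjusted over the list alone), and 28 had a log2 fold change below 0, with a median of -0.51 (95% interval -0.70 to -0.21). Without DMSO replicate 3 the median was -0.315 and 1 member rose. Camera gave an adjusted p of 2.05e-09, and the adjusted p was 0.486 with an estimated correlation. MYH7, the Z-disc proteins CSRP3 (98.6 ± 15.9 to 38.1 ± 1.87 CPM) and TCAP (39.4 ± 3.86 to 13.1 ± 2.18 CPM), and CMYA5 (148 ± 12.5 to 85.1 ± 3.19 CPM) had the smallest p. The balance of the myosin heavy chains moved as well. MYH7 reads per 100 MYH6 reads were 9.11 ± 1.4 with DMSO and 3.16 ± 0.526 with dTAGv-1 (n = 3 each). The two-sided exact permutation p was 0.1, the smallest that 3 against 3 can give. Reads that these paralogs could share were not examined. Of 8 skeletal muscle genes, ACTA1, TNNT1 and CKM fell, 0 rose and 5 did not pass (3 fell when adjusted over the list alone; camera adjusted p = 0.0136, and adjusted p = 0.296 with an estimated correlation). TNNT1 did not pass when DMSO replicate 1 or 2 or any dTAGv-1 replicate was left out (adjusted p up to 0.122), nor CKM without dTAGv-1 replicate 1 (0.107) or 2 (0.109). The count of sarcomere falls was 20 with the block, 6 without dTAGv-1 replicate 1 and 7 without replicate 2, and skeletal muscle falls numbered 1 without either of these.

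Calcium handling and ion channel genes were called lower as lists. Of 30 calcium handling genes, 7 fell, 0 rose and 23 did not pass (12 fell when adjusted over the list alone; median -0.29, camera adjusted p = 5.92e-06, and adjusted p = 0.542 with an estimated correlation). TECRL, the T-type calcium channel CACNA1G (54.4 ± 8.41 to 30.2 ± 2.70 CPM) and the channel subunit CACNA2D2 (27 ± 2.86 to 14.4 ± 1.71 CPM) were among them, as was triadin, TRDN, which did not pass when any 1 dTAGv-1 replicate was left out (adjusted p up to 0.106). Of 26 ion channel and gap junction genes, 7 fell, 1 rose and 18 did not pass (10 and 2 when adjusted over the list alone; camera adjusted p = 0.000815, and adjusted p = 0.296 with an estimated correlation). KCNIP2 (55.4 ± 5.59 to 16.2 ± 2.01 CPM), GJA5 and the pacemaker channel HCN4 (483 ± 102 to 227 ± 25.7 CPM) were among those that fell. The member that rose was KCNJ5, chosen after its values were seen. KCNJ5 did not pass when any library but DMSO replicate 3 was left out (adjusted p up to 0.0802), and without that one 2 members rose. With the block, 18 calcium handling genes fell, and 12 channel genes fell and 2 rose. Calcium handling falls numbered 3, 3 and 4 without dTAGv-1 replicates 1, 2 and 3, and the median was -0.185 without DMSO replicate 3.

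Genes near atrial fibrillation loci fell as a list, with 8 of 32 falling, 1 rising and 23 not passing (11 and 2 when adjusted over the list alone; camera adjusted p = 0.00187, and adjusted p = 0.583 with an estimated correlation). MYH7, the cell cycle inhibitor CDKN1A (152 ± 15.0 to 79.7 ± 5.06 CPM) and HCN4 were among those that fell, and KCNJ5 was again the member that rose, which it did not when any library but DMSO replicate 3 was left out (adjusted p up to 0.0802). The call was lost without DMSO replicate 3 (adjusted p = 0.112), where 5 fell and 3 rose. Falls numbered 5 without each dTAGv-1 replicate, and with the block 14 fell and 3 rose. Of 34 congenital heart disease genes, 7 fell, 1 rose and 26 did not pass (7 and 3 when adjusted over the list alone), and the list was not called (adjusted p = 0.0651). It was called lower without DMSO replicate 1 (adjusted p = 0.0299) or 2 (0.0408) or dTAGv-1 replicate 3 (0.0275), and with DESeq2, limma-voom and no filter (0.0015, 0.0337 and 0.0495). The adjusted p was 0.583 with an estimated correlation. MYH11, smooth muscle myosin, fell from 65.2 ± 6.74 to 27.7 ± 1.22 CPM and the Notch ligand JAG1 from 181 ± 12.6 to 123 ± 2.81 CPM, and KDR rose (0.60). With the block, 9 of these genes fell and 6 rose, and 5 rose without DMSO replicate 3. Falls numbered 3 without DMSO replicate 2 and 3 without each dTAGv-1 replicate, and KDR did not pass when DMSO replicate 1 or 2 or any dTAGv-1 replicate was left out (adjusted p up to 0.114).

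Of 13 sinus node markers, HCN4, CPNE5, BMP4, VSNL1 and TBX18 fell and TBX2 and RGS6 rose, with 6 not passing (6 and 2 when adjusted over the list alone). The list was not called (adjusted p = 0.0788). It was called lower without DMSO replicate 2 (adjusted p = 0.0141) or dTAGv-1 replicate 3 (0.042), and with DESeq2 and limma-voom (0.00274 and 0.0201). The adjusted p was 0.583 with an estimated correlation. RGS6 was chosen after its values were seen, and did not pass when any library but DMSO replicate 3 was left out (adjusted p up to 0.0829). CPNE5 fell from 67.7 ± 5.62 to 38.3 ± 5.28 CPM and BMP4 from 92.0 ± 7.94 to 61.0 ± 4.34 CPM. Among 30 cardiac transcription factors, TBX2 rose (396 ± 73.7 to 609 ± 61.9 CPM), HEY1 and TBX18 fell and 27 did not pass (4 rose and 5 fell when adjusted over the list alone; list adjusted p = 0.947). TBX2 did not pass without DMSO replicate 2 or dTAGv-1 replicate 1 or 2 (adjusted p = 0.0858, 0.101 and 0.0608), TBX18 without DMSO replicate 1 or 2 or dTAGv-1 replicate 2 (0.0564, 0.0694 and 0.0855), and VSNL1 without dTAGv-1 replicate 2 (0.05), where 3 sinus node markers fell. With the block, 8 of these factors rose and 7 fell, and without DMSO replicate 3, 7 rose and 2 fell. Of 16 desmosome and intercalated disc genes, LIMCH1 (-0.46) and TMEM65 (-0.37) fell and 14 did not pass (2 fell when adjusted over the list alone; list adjusted p = 0.205). LIMCH1 did not pass without DMSO replicate 2 or dTAGv-1 replicate 1 or 2 (adjusted p up to 0.116), and TMEM65 when any 1 library was left out (up to 0.195). The list was called lower without dTAGv-1 replicate 3 (0.0438; adjusted p = 0.723 with an estimated correlation over all libraries). Without DMSO replicate 3, 2 of these genes rose and 1 fell. With the block, 6 of these genes fell and 3 rose.

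**Figure D3:**
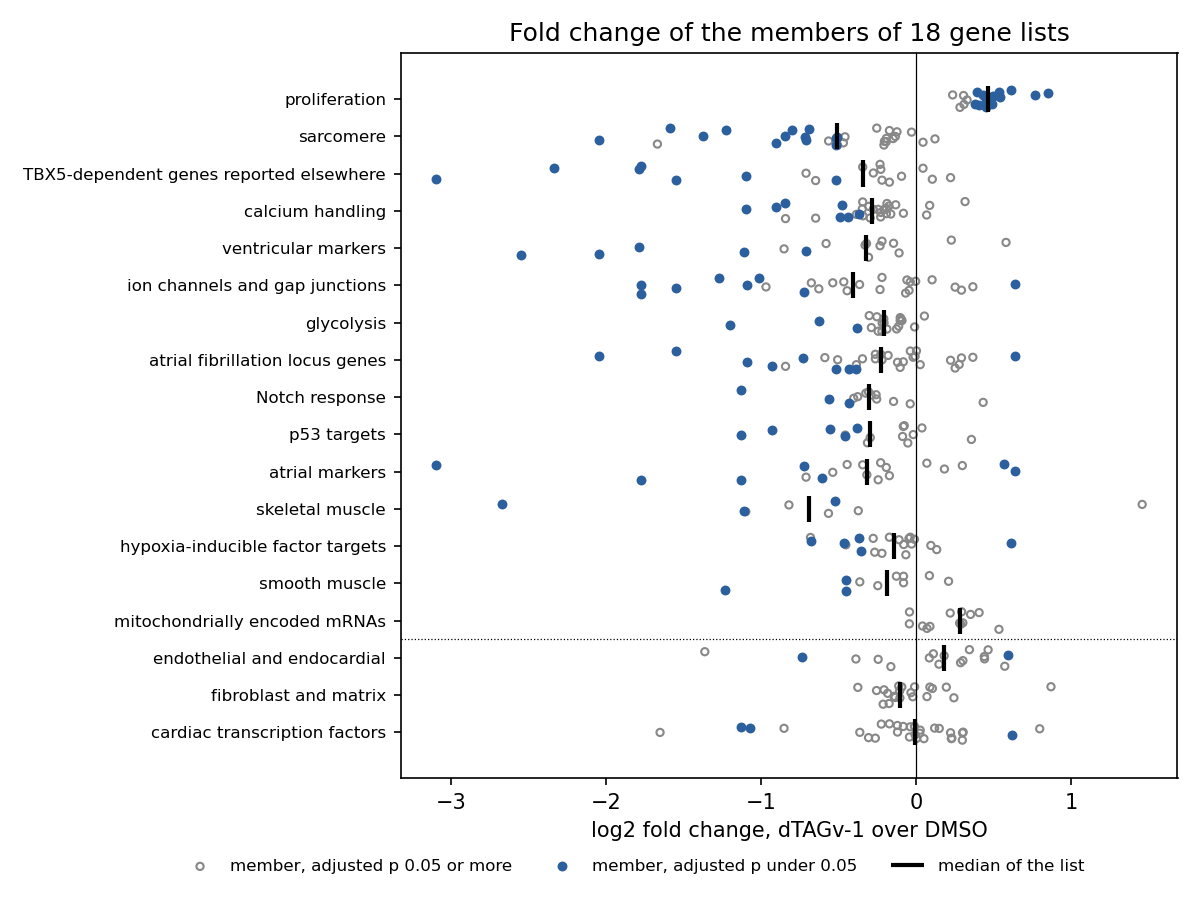
Log2 fold change of dTAGv-1 over DMSO for the members of 18 gene lists, with filled points at an adjusted p under 0.05, open points otherwise, and black bars at list medians. The 15 lists above the dotted line were called by camera with a preset correlation, 2 higher and 13 lower, and 0 of them with an estimated correlation; the median is 0.46 for proliferation and -0.51 for sarcomere genes.

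Among the metabolic lists, glycolysis genes were called lower. Of 20 glycolysis genes, the glucose transporter SLC2A4 (25.9 ± 4.98 to 11.2 ± 0.852 CPM), ALDOC (78.1 ± 15.0 to 50.5 ± 1.19 CPM) and HK2 (152 ± 20.7 to 116 ± 2.01 CPM) fell, 0 rose and 17 did not pass (5 fell when adjusted over the list alone; median -0.21, or -0.06 without DMSO replicate 3; camera adjusted p = 0.00129, and adjusted p = 0.583 with an estimated correlation). The call was lost without DMSO replicate 3 (adjusted p = 0.112), and falls numbered 1 without each dTAGv-1 replicate. ALDOC did not pass when any 1 dTAGv-1 replicate was left out (adjusted p up to 0.0714), nor HK2 then or without DMSO replicate 2 or 3 (up to 0.179). Of 24 fatty acid oxidation genes, PDK4 (-0.44) and FABP3 (-0.50) fell and 22 did not pass (3 fell when adjusted over the list alone; list adjusted p = 0.0515). Falls numbered 1 without DMSO replicate 1 and 0 when any other library was left out, while the list was called lower without DMSO replicate 1 (0.0371) or 2 (0.0198) or dTAGv-1 replicate 3 (0.044; adjusted p = 0.583 with an estimated correlation over all libraries). By edgeR, 0 of 38 nuclear oxidative phosphorylation genes passed, against 8 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (list adjusted p = 0.0673). This list too was called lower without DMSO replicate 1 or 2 or dTAGv-1 replicate 3 (0.0288, 0.0141 and 0.0432; 0.723 with an estimated correlation over all libraries). SDHA was at -0.39 (237 ± 38.1 to 181 ± 11.2 CPM). COX6A2 was at -2.13, but rests on few reads (1.08 ± 0.457 to 0.240 ± 0.120 CPM). With the block, 11 glycolysis genes fell, 7 fatty acid oxidation genes fell and 1 rose, and 9 oxidative phosphorylation genes fell and 2 rose, with both latter lists called (adjusted p = 0.0435 and 0.0398; estimated correlation, adjusted p = 0.606 for both) and SDHA (adjusted p = 8.02e-05) and COX6A2 (0.0303) passing. Mitochondrially encoded mRNAs were called higher as a list (13 tested, median 0.28, camera adjusted p = 0.0421, and adjusted p = 0.723 with an estimated correlation), but by edgeR 0 of 13 passed, against 2 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom. That call was lost without DMSO replicate 2 (adjusted p = 0.248) or 3 (0.239) or dTAGv-1 replicate 1 (0.0651) or 3 (0.286). The median was 0.503 without DMSO replicate 1, where 1 gene rose (list adjusted p = 8.46e-05), 0.16 without dTAGv-1 replicate 3 and 0.057 without both libraries numbered 3.

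Proliferation genes rose as a list. Of 23 tested members, 17 rose, 0 fell and 6 did not pass (21 rose when adjusted over the list alone), all 23 had a log2 fold change above 0, and the median was 0.46 (95% interval 0.41 to 0.49). Camera gave an adjusted p of 5.63e-14, and the adjusted p was 0.296 with an estimated correlation. The replication clamp PCNA rose from 35.4 ± 5.97 to 64.2 ± 3.18 CPM and the ribonucleotide reductase subunit RRM2 from 15.8 ± 2.60 to 27.1 ± 1.92 CPM. The mitotic genes CCNB1 (54.3 ± 4.2 to 78.6 ± 7.44 CPM) and PLK1 (35.8 ± 0.661 to 50.4 ± 3.20 CPM) rose as well. CCNB1 did not pass without DMSO replicate 2 (adjusted p = 0.0588) or dTAGv-1 replicate 1 (0.067), nor PLK1 without dTAGv-1 replicate 1 (0.0733). The number of proliferation genes that rose was 4 without DMSO replicate 2 and 2, 9 and 6 without dTAGv-1 replicates 1, 2 and 3.

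Of 15 p53 targets, 5 fell, 0 rose and 10 did not pass (7 fell when adjusted over the list alone; camera adjusted p = 0.00346, and adjusted p = 0.286 with an estimated correlation). The 5 were CDKN1A, which restrains the cell cycle, TNFRSF10B (-0.46), ZMAT3 (-0.56), PHLDA3 (-0.38) and GDF15 (-1.13), the last chosen after its values were seen and not passing when any library but DMSO replicate 3 was left out (adjusted p up to 0.168). Falls numbered 2 and 1 without DMSO replicates 1 and 2, and 1, 1 and 2 without dTAGv-1 replicates 1, 2 and 3. TNFRSF10B and PHLDA3 did not pass when any library but DMSO replicate 3 was left out (adjusted p up to 0.102 and 0.161), nor ZMAT3 without DMSO replicate 2 or dTAGv-1 replicate 1 or 2 (up to 0.114). Of 17 chromatin architecture genes, the cohesin subunit STAG1 (0.49) and the sororin gene CDCA5 (0.61) rose and 15 did not pass (2 rose when adjusted over the list alone; list adjusted p = 0.293). CDCA5 did not pass without DMSO replicate 2 or dTAGv-1 replicate 1 or 2 (adjusted p up to 0.092), nor STAG1 when any library but DMSO replicate 3 was left out (up to 0.15). With the block 3 of these genes rose.

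Notch response genes fell as a list: of 13 tested, HEY1, JAG1 and NOTCH1 (82.6 ± 5.61 to 61.1 ± 2.19 CPM) fell, 0 rose and 10 did not pass (3 fell when adjusted over the list alone; median -0.31, camera adjusted p = 0.00211, and adjusted p = 0.286 with an estimated correlation). NOTCH1 did not pass when DMSO replicate 2 or any dTAGv-1 replicate was left out (adjusted p up to 0.0947). Falls numbered 6 with the block and 5 without DMSO replicate 3. Of 19 BMP and TGF-beta response genes, the pseudoreceptor BAMBI rose (542 ± 21.5 to 781 ± 50.6 CPM), NOG (-0.70), CTGF (-0.48), TAGLN (-0.45) and SMAD9 (-0.36, chosen after its values were seen) fell and 14 did not pass (5 fell and 2 rose when adjusted over the list alone, and the same counts passed with the block; list adjusted p = 0.321). Of 14 Wnt response genes, LEF1 (0.53) and SFRP1 (0.47) rose and 12 did not pass (3 rose when adjusted over the list alone; list adjusted p = 0.33), with a median of 0.10 (0.055 without DMSO replicate 1 and 0.197 without DMSO replicate 3) and a mean of -0.02. Of 23 axon guidance genes, 5 fell, 1 rose and 17 did not pass (9 and 3 when adjusted over the list alone; list adjusted p = 0.06). The ephrin receptor EPHA4 fell from 75.3 ± 13.1 to 22 ± 1.04 CPM, and PLXNA2, NRP2 and SLIT2 fell by 0.51, 0.51 and 0.43 on the log2 scale. PLXND1 (-0.41) and EFNB1 (0.33) were chosen after their values were seen. PLXND1 did not pass when any 1 library was left out (adjusted p up to 0.185), nor EFNB1, the rise, when any but DMSO replicate 3 was (up to 0.156). With the block, 9 axon guidance genes fell and 3 rose, and the list was called (adjusted p = 0.0488; adjusted p = 0.501 with an estimated correlation), as it was without DMSO replicate 1 (0.00723) or dTAGv-1 replicate 3 (0.023), against 0.723 with an estimated correlation and no block. Leaving out 1 library ended the calls of SMAD9 (all but DMSO replicate 3, adjusted p up to 0.149), NOG (each dTAGv-1 replicate, adjusted p up to 0.0743), CTGF (DMSO replicate 2 and each dTAGv-1 replicate, up to 0.0921), TAGLN (DMSO replicate 2, dTAGv-1 replicates 1 and 2, up to 0.129), SFRP1 (all but DMSO replicate 3, up to 0.172), PLXNA2 (dTAGv-1 replicate 1, 0.0532), NRP2 (DMSO replicate 2, dTAGv-1 replicates 1 and 2, up to 0.0914) and SLIT2 (DMSO replicate 2 and each dTAGv-1 replicate, up to 0.154). Axon guidance falls numbered 2 without DMSO replicate 2 and 1, 2 and 3 without dTAGv-1 replicates 1, 2 and 3, and BMP and TGF-beta falls 1 without DMSO replicate 2 and 0, 0 and 1 without the same dTAGv-1 replicates.

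Because dTAGv-1 occupies VHL, targets of the hypoxia-inducible factors were examined: of 20, NDRG1 (106 ± 16.9 to 66.4 ± 3.56 CPM), MXI1 (-0.47), P4HA2 (-0.37) and BHLHE40 (-0.35, chosen after its values were seen) fell, PFKFB3 rose (85.3 ± 5.02 to 130 ± 4.91 CPM) and 15 did not pass (4 and 1 when adjusted over the list alone). The list was called lower (median -0.14, camera adjusted p = 0.0341, and adjusted p = 0.583 with an estimated correlation), a call lost without DMSO replicate 3 (adjusted p = 0.239) or dTAGv-1 replicate 2 (0.0738), and in 8 of 22 settings in all, among them the 5 CPM filter (0.0513), GC and length removal (0.0545) and fry (0.0743). Falls numbered 8 with the block, 2 without DMSO replicate 2 and 1, 2 and 1 without dTAGv-1 replicates 1, 2 and 3. MXI1 did not pass without dTAGv-1 replicate 1 (0.052) or 3 (0.0527), nor P4HA2 when DMSO replicate 2 or any dTAGv-1 replicate was left out (up to 0.136), nor BHLHE40 when any library but DMSO replicate 3 was (up to 0.153). Among 15 heat shock protein genes, the muscle-enriched HSPB7 (1065 ± 139 to 588 ± 16 CPM) and CRYAB (38.7 ± 6.94 to 18.9 ± 1.75 CPM) fell, DNAJA1 (0.55) and HSPA8 (0.39) rose and 11 did not pass (2 and 3 when adjusted over the list alone; list adjusted p = 0.32). Of 19 genes of the unfolded protein and integrated stress response, SDF2L1 (0.73) and PDIA4 (0.37) rose and 17 did not pass (3 rose when adjusted over the list alone; list adjusted p = 0.215). Of 26 immediate early genes, EGR1 rose, CTGF fell and 24 did not pass (3 and 1 when adjusted over the list alone; list adjusted p = 0.297). Of 16 interferon-stimulated genes, IFIT2 rose (0.352 ± 0.114 to 1.4 ± 0.411 CPM) and 15 did not pass (2 rose when adjusted over the list alone; list adjusted p = 0.185). IFIT2 passed by edgeR (adjusted p = 0.0435) but not by limma-voom (0.0656), DESeq2 gave it no adjusted p, and 11 of 19 settings lost the call. Leaving out 1 library ended the calls of DNAJA1 (DMSO replicate 2, dTAGv-1 replicate 2, adjusted p = 0.0537 and 0.0511), of CTGF (DMSO replicate 2 and each dTAGv-1 replicate, up to 0.0921) and, for every library but DMSO replicate 3, of HSPA8, SDF2L1, PDIA4 and IFIT2 (up to 0.112, 0.0891, 0.111 and 0.217). With the block, 6 heat shock genes rose and 3 fell, 4 unfolded protein response genes rose and 2 fell, 6 immediate early genes rose and 2 fell, and 2 interferon-stimulated genes rose. Rises numbered 4 for both heat shock and unfolded protein response genes without DMSO replicate 3, and for immediate early genes 3 without DMSO replicate 1 and 2 without DMSO replicate 3.

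Of the fibroblast, smooth muscle, endothelial and epicardial lists, smooth muscle alone was called, and it was lower. By edgeR, 0 of 21 fibroblast and matrix genes passed, against 4 at an unadjusted p under 0.05, 0 by DESeq2 and 0 by limma-voom (median -0.10, or -0.062 without DMSO replicate 3 and -0.023 without dTAGv-1 replicate 1; list adjusted p = 0.445). LOX was at -0.38 and TCF21 at 0.87. With the block, 6 fibroblast genes fell and 0 rose, LOX among them (adjusted p = 0.000229). Of 10 smooth muscle genes, MYH11, MYLK (-0.45) and TAGLN (-0.45) fell, 0 rose and 7 did not pass (4 fell when adjusted over the list alone; camera adjusted p = 0.04, and adjusted p = 0.542 with an estimated correlation). That call was lost without DMSO replicate 3 (adjusted p = 0.18) or dTAGv-1 replicate 1 (0.0545) or 2 (0.0948), without both libraries numbered 3 (0.129), and with the GC and length trend removed (0.0717, or 0.0726 with the block). With the block 1 of these genes rose, as 1 did without DMSO replicate 3. Falls numbered 5 with the block and 1 without DMSO replicate 2 or dTAGv-1 replicate 1 or 2, where MYLK (up to 0.106) and TAGLN (up to 0.129) did not pass. Of 17 endothelial and endocardial genes, KDR rose (79.6 ± 17.5 to 120 ± 7.84 CPM), NPR3 fell (41.7 ± 7.79 to 25.1 ± 0.833 CPM) and 15 did not pass (1 and 1 when adjusted over the list alone; median 0.18, and 0.051 to 0.492 over the single libraries left out; list adjusted p = 0.33). The lowest was without DMSO replicate 2 and the highest without DMSO replicate 3, where 2 rose. With the block, 2 of them rose and 2 fell. KDR did not pass when DMSO replicate 1 or 2 or any dTAGv-1 replicate was left out (up to 0.114). Of 11 epicardial genes, ALDH1A2, which makes retinoic acid, fell from 16.9 ± 2.87 to 7.59 ± 0.727 CPM, TBX18 fell and 9 did not pass (2 fell when adjusted over the list alone; median -0.30, or -0.177 and -0.466 without dTAGv-1 replicates 1 and 2; list adjusted p = 0.0651). This list was called lower without dTAGv-1 replicate 3 (0.00451; 0.583 with an estimated correlation over all libraries). TBX18 did not pass without DMSO replicate 1 or 2 or dTAGv-1 replicate 2 (0.0564, 0.0694 and 0.0855).

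Of 20 endoderm and hepatic genes, EPCAM fell (-0.34) and 19 did not pass (1 fell when adjusted over the list alone; median 0.23, from -0.008 without dTAGv-1 replicate 2 to 0.42 without DMSO replicate 3; list adjusted p = 0.477). With the block 2 fell, and without DMSO replicate 3, 3 rose and 1 fell. EPCAM did not pass when any library but DMSO replicate 3 was left out (adjusted p up to 0.199). By edgeR, 0 of 11 neural and neural crest genes passed, against 1 at an unadjusted p under 0.05, 1 by DESeq2 and 0 by limma-voom (1 fell when adjusted over the list alone; median 0.22, from -0.211 without dTAGv-1 replicate 2 to 0.345 without DMSO replicate 2; list adjusted p = 0.402), and 0 of 8 pluripotency genes passed, against 1, 1 and 0 in the same order (list adjusted p = 0.435). TFAP2A was at -0.51 and ZFP42 at -1.24 on the log2 scale. Both passed as falls with the block (adjusted p = 0.00209 and 0.0247), as 1 other neural gene did as a rise, and TFAP2A also without DMSO replicate 3 (-0.64, adjusted p = 0.00234). The tested macrophage and blood genes were CSF1R, at 2.25 ± 0.416 and 2.47 ± 0.221 CPM, and PTPRC, at 2.57 ± 3.04 and 3.75 ± 3.87 CPM (adjusted p = 0.85 and 0.87).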

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

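Alternatives chosen after seeing the data were leaving out both libraries numbered 3, thinning to the smallest total, removing the GC and length trend, and that removal with the block; the others were planned. TBX5 kept its rise and its call in all 20 settings, with log2 fold changes of 0.608 to 0.858 and adjusted p up to 0.0317. Of 97 called named genes, 53 kept their call in every setting, 9 lost it only when 1 library was left out and 35 in at least 1 other setting; in 1937 comparisons 1688 stayed called in the same direction, 249 lost the call and 0 turned. Of 513 comparisons of the 26 uncalled named genes, 452 stayed uncalled in the same direction, 53 passed and 8 turned: NKX2-5 (-0.002 with the 5 CPM filter, -0.038 and -0.087 without DMSO replicates 1 and 2, -0.074 without dTAGv-1 replicate 3), CSF1R (-0.009) and SMYD1 (-0.04) without DMSO replicate 2, PTPRC (-0.663) without dTAGv-1 replicate 2 and DSP (0.023) without DMSO replicate 3. Over the single libraries left out, NKX2-5 spanned -0.087 to 0.193, CSF1R -0.009 to 0.27, PTPRC -0.663 to 2.213, DSP -0.188 to 0.023 and SMYD1 -0.04 to 0.214. Counts of rises and falls, main values 482 and 675, were 797 and 1147 with no filter, 306 and 298 from FPKM with a pseudocount of 1, 313 and 290 with 0.1, 1625 and 2084 with the block and 2171 and 1716 with the block and GC; DESeq2 gave 742 rises and GC removal 426 falls. At least 2-fold, main values 48 and 139, they were 27 and 91 at 5 CPM, 8 and 43 from FPKM with a pseudocount of 1, 131 and 238 with the block and 154 and 213 with the block and GC, and rises numbered 86 with no filter. Leaving out 1 library gave 117 to 895 rises, 209 to 870 falls, 24 to 75 and 84 to 160 at least 2-fold, and 1 to 2 lists higher and 8 to 20 lower. Of the 2 lists called higher, 1 remained with the 5 CPM filter, with protein-coding genes alone, without both libraries numbered 3, with GC removed and with block and GC; proliferation was the one that stayed. With an estimated correlation 0 lists were called higher and 0 lower, against 2 and 13, and fry called 1 higher and 8 lower. For Notch response, p53 and skeletal muscle genes the estimated correlation was 0.001, -0.004 and -0.057, not above the preset 0.01. Higher correlation therefore does not account for the loss of these list calls. Beyond single libraries and the estimated correlation, fry ended the calls of calcium handling (adjusted p = 0.0595), atrial (0.131), glycolysis (0.131), atrial fibrillation (0.0937), hypoxia (0.0743) and mitochondrially encoded genes (0.558). Leaving out both libraries numbered 3 ended those of glycolysis (0.0686), hypoxia (0.237), smooth muscle (0.129) and mitochondrially encoded genes (0.711). The last 3 lists also lost theirs with GC removed (0.0545, 0.0717 and 0.0534) and with block and GC (0.0518, 0.0726 and 0.0543), hypoxia and mitochondrially encoded genes with the 5 CPM filter (0.0513 and 0.053), and the latter with protein-coding genes alone (0.0579). Of 20 uncalled lists, 7 were called lower in at least 1 setting: fatty acid oxidation in 10 of 22, axon guidance in 7, epicardial and congenital heart disease genes in 6 each, oxidative phosphorylation in 5, sinus node markers in 4 and desmosome genes in 1. Of the calls of named genes, FPKM ended 30 with a pseudocount of 1 and 29 with 0.1, GC removal 18, leaving out both libraries numbered 3 ended 5, RLE and limma-voom 4 each, and DESeq2 and thinning 1 each. The block changed no call of a gene or list named in the report other than those given beside the results. The cause was not tested. Genes near the filter, such as IFIT2, at 0.352 CPM with DMSO, rest on few reads.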

Other observations

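The tests of TBX5-AS1 reads, of a lower share of cardiomyocytes and of VHL occupation were chosen only after the results they concern were seen, as were the thinned and the GC-corrected fits; the other tests were written before their result was seen. Neighbouring genes tended to change together. Among 15070 adjacent pairs of tested genes that do not overlap, 47 had both members called in the same direction, against a median of 27 (18 to 37 in 95% of 10000 shuffles of the calls, permutation p = 3e-04). Shuffling within 10 classes of mean CPM gave a median of 28 (18 to 39, permutation p = 9e-04). NPPA with NPPB and MYH6 with MYH7 were such pairs, both lower, although MYH6 did not pass when any 1 library was left out. Some pairs are paralogs that could share reads, which was not tested. Among these are MYH6 with MYH7, and TUBA1B with TUBA1A, the latter both higher and chosen after their values were seen. Whether neighbours share regulation stays a hypothesis.

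Genes of transcription factors, as the deposited file assigns them to a family, were hypothesised to change more often than others, and did not. Of 1243 tested, 59 were called (4.75%), against 1035 of 13888 other protein-coding genes (7.45%), an odds ratio of 0.62 (95% interval 0.46 to 0.81, Fisher's exact p = 0.000246). Over 10 classes of mean CPM the Mantel-Haenszel odds ratio was 0.63 (0.48 to 0.83).

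The rise of TBX5 mRNA was weighed against reads of TBX5-AS1 counted to TBX5 and a gain of chromosome 12. The 1008 other tested genes of chromosome 12 had a median log2 fold change of -0.012 with an upper 95% bound of 0.009, far below what a gained copy needs, so the tables argue against a gain. Over 9 pairings of a DMSO with a dTAGv-1 library, the rise of TBX5 was 0.98 to 2.34 times the whole level of TBX5-AS1 under dTAGv-1. The 3 same-numbered pairs, tested after those 9 pairings were seen, gave 1.93, 1.86 and 1.55, a mean of 1.78 with a 95% interval of 1.27 to 2.29. The exons share 252 bases, 5.8% of those of TBX5 and 6% of those of TBX5-AS1. Reads counted to TBX5 are not in the TBX5-AS1 count, and the pairing was read from these data, so these ratios set no strict bound. TBX5-AS1 was at 51.0 CPM under dTAGv-1, while TBX5 went from 144 to 234 CPM. With so few shared bases, these levels argue against reads of annotated TBX5-AS1 as the whole rise. Antisense reads from outside its annotated exons were not examined. Antisense reads as a part of the rise stay open, since the counting strand is not given in the sources used here. A response of the TBX5 gene to loss of its protein was not tested.

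For the rise of proliferation genes, depth, base composition and a lower share of cardiomyocytes were weighed. Thinned to the smallest library, the list's median was 0.458 against 0.463, with 17 members still called. Random thinning leaves the expected share of each gene unchanged, so this median could hardly move. The thinned fit shows only that the calls did not need the extra reads, and does not decide on depth. With the GC and length trend removed the median was at least 0.467, with 15 called, or 21 with the block. The tables therefore argue against base composition and transcript length. If markers followed cell numbers alone, a lower share of cardiomyocytes would raise those of every other cell type alike. Cell composition was not measured. The medians of endothelial, endoderm and neural genes were above 0, at 0.182 (95% interval -0.163 to 0.441), 0.226 (-0.139 to 0.331) and 0.217 (-0.137 to 0.46), but over the single libraries left out they ran from 0.051 to 0.492, -0.008 to 0.42 and -0.211 to 0.345, so those of endoderm and neural genes changed sign. Those of smooth muscle and epicardial genes were below 0, at -0.187 (-0.449 to 0.003) and -0.304 (-0.973 to 0.05). The fibroblast median was -0.104, and -0.145 to -0.023 over the single libraries left out, so these genes showed no rise as a list. Its upper 95% bound of -0.009 comes from resampling genes with an estimated correlation of 0.532, and does not measure the spread between libraries. With medians on both sides of 0 among the other lists, the tables do not decide on a lower share of cardiomyocytes. Of the 22 genes of the fibroblast list, 21 were expressed highly enough to be tested, and TCF21 is also an epicardial marker. More endothelial, endoderm or neural cells, or growth of 1 dividing cell type, also remain open. No list separates dividing cardiomyocytes from other dividing cells.

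For the fall of sarcomere genes, a lower share of cardiomyocytes and occupation of VHL were weighed. For the first, the fibroblast list showed no rise, with a median of -0.104. Its bound of -0.009 does not measure the spread between libraries. Medians of the other marker lists, as given before, lay on both sides of 0, so the tables do not decide on the first. Whether 500 nM of the ligand keeps VHL from the hypoxia-inducible factors was not measured. If it did, targets of these factors should rise. Their median was -0.141, and -0.189 to -0.102 over the single libraries left out, so they showed no rise as a list, although PFKFB3 rose. The upper 95% bound of -0.042 comes from resampling genes and does not measure the spread between libraries. VHL occupation itself was not measured, and its part in the fall of sarcomere genes is not decided. Effects of the ligand apart from TBX5 stay open, since untagged cells given dTAGv-1 are not analysed here.

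The 6 libraries form 10 splits of 3 against 3, too few for a share under 0.05. The real split called 1157 genes, 187 of them at least 2-fold, and the highest other split 33 and 33, so 1 of 10 reached each count. For lists, 2 of 10 splits reached the real count of 15: DMSO replicates 1 and 3 with dTAGv-1 replicate 3 against the rest gave 19. The remaining splits called 0 genes but 3 to 14 lists each. List calls with the preset correlation therefore also arose where the groups were mixed, and such a call alone does not set the groups apart. Among the 4 splits that part all 3 pairs of numbers, the other 3 called 0 genes, also with the block, where the real split called 3709, and 3, 5 and 6 lists.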
